A study of Mus musculus with 40 samples.

How the data were processed

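The analysis started from the gene-level tables deposited for each of 40 libraries, which hold RSEM expected counts and TPM for 54752 gene IDs. Per the labels, RNA came from neural retina of C57BL/6/129 mice and TruSeq RNA v2 libraries, which do not mark the strand, were sequenced paired-end on an Illumina HiSeq. The submitters' processing notes name bcl2fastq 2.20.0.422, STAR 2.6.1d, RSEM 1.3.1 and mm10, without an annotation release. IDs were matched by stable ID to GENCODE M21, which supplied symbols, positions and 3' UTRs: 54723 matched, 53861 with the same version. The genotype label writes Zfp36l1 at both positions while the series text names both genes, so the second was read as Zfp36l2. At E17.5 the genotypes in the file names of both replicate 1 libraries are opposite to the labels, and the labels were used.

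Expected counts were rounded and analysed at each stage in a fit of 8 libraries with edgeR 4.0.16 (filterByExpr, TMM factors, quasi-likelihood F test, Benjamini-Hochberg adjustment, calls at 0.05), in R 4.3.3. Differences between consecutive stages came from the interaction term in fits of 16 libraries. The 35 gene lists, fixed before any value was seen, were tested with limma 3.58.1 camera at a correlation of 0.01, adjusted over the lists, and again with an estimated correlation. They cover retinal cell types, neighbouring tissues, cell cycle, signalling, stress, metabolism and reported ZFP36 targets. Separation means that all 4 DKO values lie above or below all 4 controls. Genes named in the text were drawn by a rule fixed beforehand: the targeted genes and Zfp36, then the 8 largest changes per direction and stage among called, separated genes with a mean TPM of 1 or more, and up to 4 called members of each list with the smallest adjusted p. Interactions and genes called at all stages were named by smallest adjusted p. Gm36660, the chromosome 9 window and the libraries in doubt were chosen after their values were seen.

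Genes with 2 or more UAUUUAU in the longest annotated 3' UTR were matched without replacement to genes with 0 on 3' UTR length and expression within a caliper of 0.25 SD, and groups were compared by exact permutation of libraries. This used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9.

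In a self-test on simulated counts with 200 changed genes per stage, edgeR recovered 46.3% to 73.1% of genes changed 1.5-fold, 80.6% to 91.0% of those changed 2-fold and 93.9% to 97.0% of those changed 4-fold, with 7 to 16 false calls. The interaction test recovered 47.8%, 83.6% and 97.0%, with 15 false calls. Alternatives tried were DESeq2 1.42.0, median-of-ratios factors, no or a stricter low-count filter, limma on log2(TPM + 1) and log2(TPM + 0.1), all 40 libraries in one fit, the replicate number as a block, a 1.5-fold threshold, fry, other motif definitions and leaving out each library. Removal of each library's trend over gene length and leaving out libraries in doubt were added after the data were seen. The libraries in doubt were E14.5 control 4, E17.5 control 4 and DKO 1, the library labelled P0 control 2, the libraries labelled P5 DKO 1 and DKO 3, and P16 DKO 1. Deviations of genes from group means correlated at -0.25 to 0.23 between same-numbered libraries of the 2 genotypes, so reported fits did not pair them.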

Results

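RNA was sequenced from the neural retina of mice at 5 stages: embryonic days 14.5 and 17.5 (E14.5, E17.5) and postnatal days 0, 5 and 16 (P0, P5, P16). At each stage 4 control libraries with floxed alleles were set against 4 libraries labelled as double knockout (DKO) of Zfp36l1 and Zfp36l2 by Vsx2-Cre, which is expressed in retinal progenitors. Both genes encode RNA-binding proteins of the ZFP36 family, which bind AU-rich elements in 3' untranslated regions (3' UTRs) and promote decay of the mRNAs that carry them. The comparison asks which transcripts differ. No control label names Cre, so deletion and Cre transgene effects were not separated. Total expected counts per library ran from 5.043 to 29.216 M (median 10.7 M). Values below are library-scaled counts (CPM) as mean ± SD with n = 4 libraries per group, or log2 fold changes of DKO over control ± SE with edgeR's adjusted p. For each gene list the text gives the tested members that rose, fell or did not pass, the median log2 fold change, the number of DKO libraries whose list mean lay beyond every control, and camera's adjusted p. Camera called 15, 12, 15, 15 and 15 lists from E14.5 to P16 and, with a correlation estimated from the data, 0 at each stage. Nothing in the labels says that the 4 libraries of a group came from separate animals, so p-values measure only the spread between these libraries.

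Zfp36l1 (chromosome 12, 80107754 to 80113013, mm10) was lower in DKO libraries through P0 and at a similar level afterwards. At E14.5 the controls held 34.0 to 46.5 CPM and the DKO libraries 15.6 to 24.6 CPM (-0.97 ± 0.14, adjusted p = 0.00227). The ranges at E17.5 were 79.3 to 97.2 against 32.9 to 54.8 CPM (-1.07 ± 0.14, adjusted p = 0.000809), and at P0 66.4 to 97.1 against 49.3 to 63.5 CPM (-0.58 ± 0.11, adjusted p = 0.01). No difference passed at P5, with 27.8 to 37.8 against 26.5 to 33.8 CPM (-0.07 ± 0.12, adjusted p = 0.809), or at P16, with 4.36 to 6.26 against 5.81 to 8.96 CPM (0.39 ± 0.17, adjusted p = 0.153). In control retinas Zfp36l1 itself changed over the 5 stages (edgeR adjusted p = 7.8e-15), from a mean of 90.3 CPM at E17.5 to 5.58 CPM at P16. The labels do not say which part of either gene the floxed segment spans, and the counts cover whole genes.

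Zfp36l2 (chromosome 17, 84183931 to 84187947) was lower in every DKO library than in every control at E14.5, with 23.4 to 35.05 against 6.16 to 14.2 CPM (-1.32 ± 0.22, adjusted p = 0.0038), and at E17.5, with 60.3 to 73.5 against 20.02 to 49.8 CPM (-0.96 ± 0.19, adjusted p = 0.00598). At P0 the library labelled control 2 held 4.08 CPM, while the other 3 controls held 60.6 to 128 CPM and the DKO libraries 31.9 to 93.9 CPM, DKO 2 within the range of those 3 controls (-0.49 ± 0.61, adjusted p = 0.641). At P5 the libraries labelled DKO 1 and DKO 3 held 21.6 and 31.4 CPM, DKO 2 and DKO 4 held 3.09 and 3.30 CPM, and the controls 24.7 to 32.7 CPM (-0.92 ± 0.57, adjusted p = 0.442). Zfp36l2 fell at P16, from 21.6 to 43.0 CPM in controls to 9.58 to 23.6 CPM in DKO libraries (-1.29 ± 0.32, adjusted p = 0.0293), although DKO 1 at 23.6 CPM lay within the control range. That call was lost without any 1 of control 2, control 3, DKO 2, DKO 3 or DKO 4, with a highest adjusted p of 0.0994 without DKO 3. All directions are drawn with every library in the group its label gives.

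**Figure D1:**
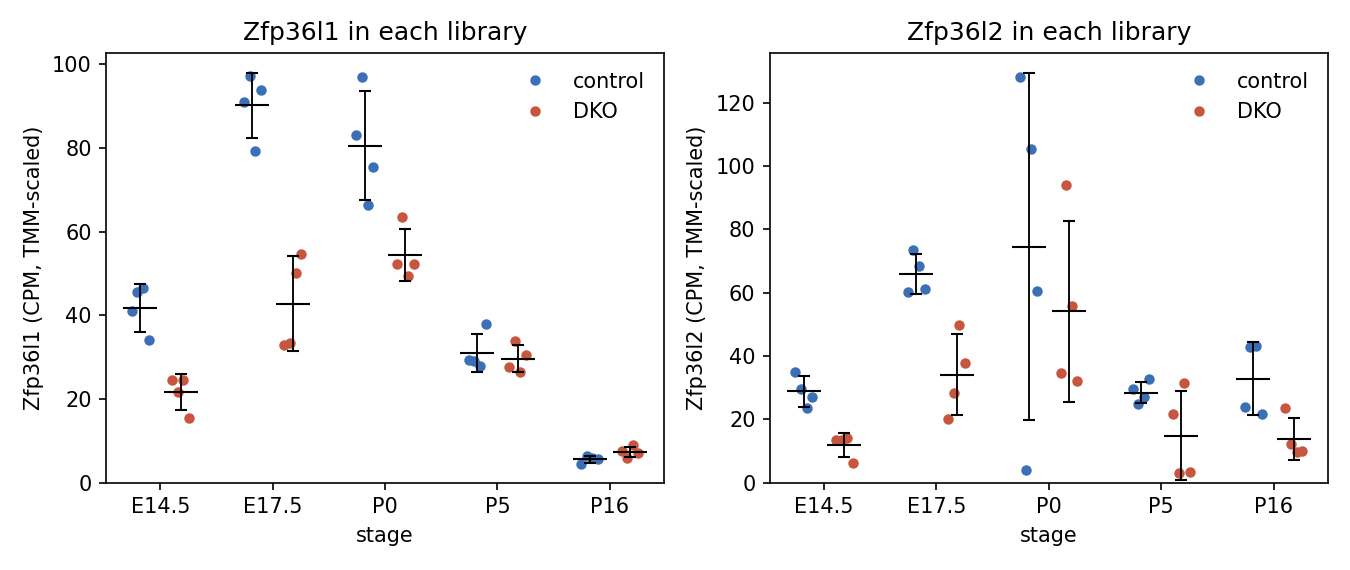
CPM of Zfp36l1 and Zfp36l2 in each of the 40 libraries by stage, with points for control and DKO libraries and bars for the mean ± SD of 4. For Zfp36l2 the library labelled control 2 at P0 sits at 4.08 CPM and the libraries labelled DKO 1 and DKO 3 at P5 sit at 21.6 and 31.4 CPM.

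A predicted lincRNA gene downstream of Zfp36l1 on the same strand, Gm36660 (chromosome 12, 80018415 to 80081434), followed the labels in every library and was looked at after its values were seen. Control libraries held 0 to 0.865 CPM and DKO libraries 69.2 to 120.2 CPM at E14.5, 113.1 to 222.6 CPM at E17.5, 27.3 to 110.6 CPM at P0, 21.1 to 38.5 CPM at P5 and 1.24 to 39.2 CPM at P16. The library labelled control 2 at P0 held 0.0801 CPM and the libraries labelled DKO 1 and DKO 3 at P5 held 23.3 and 38.5 CPM. In both E17.5 replicate 1 libraries, whose file names give the opposite genotype, expression went with the label. Zfp36l1 stood at 90.9 CPM in control 1 and 32.9 CPM in DKO 1, and Gm36660 at 0 and 222.6 CPM. The paralog Zfp36 (chromosome 7, 28376784 to 28380253), an immediate early gene of the same family, rose at E14.5 (0.94 ± 0.22, adjusted p = 0.0166) but not without control 1 (adjusted p = 0.056) or DKO 4 (adjusted p = 0.0511). Its adjusted p was 0.744 at E17.5, 0.71 at P0, 0.96 at P5 and 0.0915 at P16. Over the control stages Zfp36l2 gave an adjusted p of 0.0473 (0.0504 with median-of-ratios size factors) and Zfp36 an adjusted p of 0.193.

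At E14.5, when progenitors divide and the first neurons form, several genes of neurons born early rose in the DKO group. Cyp26c1, an enzyme that breaks down retinoic acid (chromosome 19, 37685581 to 37693398), rose from 0.494 ± 0.113 to 5.10 ± 0.709 CPM (3.36 ± 0.21, adjusted p = 7.64e-06). Fgf15, a growth factor made by retinal progenitors (chromosome 7, 144896531 to 144900953), rose from 923 ± 49.5 to 2413 ± 332 CPM (1.39 ± 0.09, adjusted p = 1.53e-05). Rises were also seen for the transglutaminase gene Tgm2 (1.61 ± 0.10, adjusted p = 6.93e-06), the homeodomain protein gene Hopx (1.41 ± 0.12, adjusted p = 0.000117) and the vesicle coat gene Sec24d (1.42 ± 0.16, adjusted p = 0.000648). Among genes that fell were the haem-binding protein gene Hebp1 (-0.97 ± 0.18, adjusted p = 0.0057) and the glutathione transferase gene Gstm2 (-0.98 ± 0.22, adjusted p = 0.016). The interferon-inducible GTPase gene Igtp showed the largest fall (-2.23 ± 0.66, adjusted p = 0.0448), with 14.9 CPM in control 4 and 1.53 to 2.70 CPM in the other controls. Leaving out 1 library ended the call of Igtp (adjusted p = 0.119 without DKO 2).

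At E14.5, of the retinal ganglion cell list, 9 of 18 rose, 0 fell and 9 did not pass (16 up, 0 down adjusted over the list alone), among them the transcription factors Pou4f1 (0.89 ± 0.10, adjusted p = 0.000648), Isl2 (0.81 ± 0.11, adjusted p = 0.00165) and Isl1 (0.42 ± 0.07, adjusted p = 0.0045). That list had a median of 0.25, a mean above every control in 4 of 4, camera adjusted p = 3.87e-08 and 0.289 at an estimated correlation. For neurogenic transcription factors, 12 of 20 rose, 0 fell and 8 did not pass (13 up, 0 down adjusted over the list alone), including Bhlhe22 (0.56 ± 0.07), Insm1 (0.51 ± 0.07) and the amacrine and horizontal cell determinant Ptf1a (0.39 ± 0.08). These factors had a median of 0.27, a mean above every control in 4 of 4, camera adjusted p = 1.2e-07 and 0.123 at an estimated correlation. In the amacrine cell list 5 of 8 rose, 0 fell and 3 did not pass (5 up, 0 down adjusted over the list alone), led by the calcium-binding protein gene Calb2 (0.57 ± 0.08) and Tfap2b (0.70 ± 0.15). The amacrine list had a median of 0.43, a mean above every control in 4 of 4, camera adjusted p = 0.00504 and 0.193 at an estimated correlation. On log2(TPM + 1), where tested members can differ (here and below), the median was 0.02, and -0.11 over all genes. For the rod list 3 of 9 rose, 0 fell and 6 did not pass (4 up, 0 down adjusted over the list alone), with Rbp3, the interphotoreceptor retinoid-binding protein, at 0.47 ± 0.08. The rod list had a median of 0.31, a mean above every control in 4 of 4, camera adjusted p = 0.0102 and 0.193 at an estimated correlation. Of the cone list, 1 of 9 rose, 0 fell and 8 did not pass (2 up, 0 down adjusted over the list alone), the riser being the short-wave opsin Opn1sw (1.34 ± 0.35). Cone genes had a median of 0.36, a mean above every control in 4 of 4, camera adjusted p = 0.0116 and 0.394 at an estimated correlation. The cone list did not pass without control 3 (adjusted p = 0.0515). Single libraries decided the call of Opn1sw (adjusted p = 0.0791 without control 1).

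Genes of blood and vessels were higher in DKO libraries at the same stage. Of the erythroid list 8 of 10 rose, 0 fell and 2 did not pass (9 up, 0 down adjusted over the list alone), with the alpha globin gene Hba-a1 going from 86.2 ± 11.3 to 178 ± 8.90 CPM (1.05 ± 0.09, adjusted p = 7.63e-05) and the haem synthesis gene Alas2 at 0.92 ± 0.12. The erythroid list had a median of 1.04, a mean above every control in 4 of 4, camera adjusted p = 3.08e-09 and 0.193 at an estimated correlation. Of endothelial genes, 8 of 14 rose, 0 fell and 6 did not pass (12 up, 0 down adjusted over the list alone), among them the tight junction gene Cldn5 (1.33 ± 0.09) and the VEGF receptor gene Kdr (0.69 ± 0.10). Endothelial genes had a median of 1.07, a mean above every control in 4 of 4, camera adjusted p = 2.29e-07 and 0.353 at an estimated correlation. Of the mural and fibroblast list 1 of 12 rose, 0 fell and 11 did not pass (5 up, 0 down adjusted over the list alone). Mural and fibroblast genes had a median of 0.61, a mean above every control in 3 of 4, camera adjusted p = 0.0344 and 0.523 at an estimated correlation. On log2(TPM + 1) the median was -0.08, and -0.11 over all genes. The mural list did not pass without control 1 (adjusted p = 0.0638), control 2 (adjusted p = 0.127), DKO 1 (adjusted p = 0.0582) or DKO 4 (adjusted p = 0.106). Of the pigment epithelium list 2 of 12 rose, 0 fell and 10 did not pass (3 up, 0 down adjusted over the list alone), the risers being the melanin synthesis genes Dct (0.96 ± 0.20) and Pmel (0.63 ± 0.15). Pigment epithelium genes had a median of 0.41, a mean above every control in 4 of 4, camera adjusted p = 0.0425 and 0.394 at an estimated correlation. This list did not pass without control 2 (adjusted p = 0.0646), control 3 (adjusted p = 0.0813) or DKO 3 (adjusted p = 0.0623). In the hypoxia and glycolysis list 7 of 21 rose, 0 fell and 14 did not pass (10 up, 0 down adjusted over the list alone), among them Ndrg1 (0.51 ± 0.06) and the collagen prolyl hydroxylase gene P4ha1 (0.80 ± 0.14). Hypoxia and glycolysis genes had a median of 0.30, a mean above every control in 2 of 4, camera adjusted p = 1.16e-06 and 0.394 at an estimated correlation.

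Genes that copy DNA were lower. Of the DNA replication list 2 of 22 rose, 11 fell and 9 did not pass (4 up, 15 down adjusted over the list alone). The helicase genes Mcm5 (-0.39 ± 0.06) and Mcm6 (-0.33 ± 0.06) fell with Gins2 (-0.46 ± 0.07), whereas the ribonucleotide reductase gene Rrm2 rose (0.86 ± 0.10). The list had a median of -0.21, a mean below every control in 4 of 4, camera adjusted p = 0.000306 and 0.353 at an estimated correlation. For replication-dependent histones 0 of 16 rose, 7 fell and 9 did not pass (0 up, 12 down adjusted over the list alone). Replication-dependent histone genes had a median of -0.26, a mean below every control in 3 of 4, camera adjusted p = 2.4e-06 and 0.394 at an estimated correlation. Of ribosomal protein genes, 0 of 30 rose, 3 fell and 27 did not pass (0 up, 16 down adjusted over the list alone). Ribosomal protein genes had a median of -0.21, a mean below every control in 3 of 4, camera adjusted p = 4.85e-08 and 0.452 at an estimated correlation. Of the interferon response list 0 of 8 rose, 2 fell and 6 did not pass (0 up, 5 down adjusted over the list alone), Oasl2 among those that fell (-1.47 ± 0.30). Interferon response genes had a median of -0.91, a mean below every control in 4 of 4, camera adjusted p = 0.0012 and 0.394 at an estimated correlation. On log2(TPM + 1) the median was -0.45, and -0.11 over all genes. In the integrated stress and unfolded protein list 5 of 21 rose, 1 fell and 15 did not pass (6 up, 1 down adjusted over the list alone), led by the endoplasmic reticulum chaperone Hspa5 (0.51 ± 0.06) and the transcription factor Xbp1 (0.26 ± 0.06). Integrated stress and unfolded protein genes had a median of 0.10, a mean above every control in 4 of 4, camera adjusted p = 0.0116 and 0.394 at an estimated correlation.

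Over 14351 tested genes, edgeR called 1913 at E14.5, 1046 higher and 867 lower in DKO libraries. Among them 108 changed at least 2-fold (91 up, 17 down). An unadjusted p under 0.05 was reached by 4311 genes, and 20% of tested genes had groups that did not overlap, against 2 of 70 orderings by chance. The count was 1017 without control 1, 962 without DKO 2 and 913 without DKO 4, and 2013 without control 4, which stood apart on a principal component. Limma on log2(TPM + 1) called 47 genes, 29 up and 18 down.

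By E17.5 rod photoreceptor genes led the rise. Nr2e3, a nuclear receptor of rod precursors (chromosome 9, 59942771 to 59960659), went from 3.10 ± 2.18 to 27.8 ± 9.54 CPM (3.08 ± 0.35, adjusted p = 0.000492), and rod arrestin Sag (chromosome 1, 87803680 to 87845158) from 0.903 ± 0.213 to 5.83 ± 1.87 CPM (2.67 ± 0.28, adjusted p = 0.000492). Samd7, a rod chromatin protein gene, rose as well (2.22 ± 0.35, adjusted p = 0.00177), with Ppp1r1b, a dopamine-regulated phosphatase inhibitor gene (2.72 ± 0.31, adjusted p = 0.000492), and the myelin glycoprotein gene Omg (2.52 ± 0.42, adjusted p = 0.00217). Counts of the secretin gene Sct were low, 6 over the 4 controls and 54 over the DKO libraries, a ratio of 7.70 with a 95% interval of 3.32 to 21.9 that covers counting error only. Genes that fell included the transcription factor Glis3 (-1.20 ± 0.28, adjusted p = 0.0118), the cholinesterase gene Bche (-1.15 ± 0.27, adjusted p = 0.014), the matrix gene Efemp1 (-1.07 ± 0.16, adjusted p = 0.00139), the amino acid transporter gene Slc7a3 (-1.06 ± 0.15, adjusted p = 0.00108) and the RNA-binding protein gene Samd4 (-1.02 ± 0.18, adjusted p = 0.00312).

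In the rod list 12 of 16 rose, 0 fell and 4 did not pass (13 up, 0 down adjusted over the list alone). Besides Nr2e3 and Sag these included Nrl, the transcription factor that sets rod fate (1.74 ± 0.19), and the phosphodiesterase subunit Pde6b (4.25 ± 0.60). Rod genes had a median of 1.27, a mean above every control in 4 of 4, camera adjusted p = 6.6e-10 and 0.416 at an estimated correlation. Of the amacrine list 7 of 13 rose, 0 fell and 6 did not pass (10 up, 0 down adjusted over the list alone), among them neuropeptide Y, Npy (2.22 ± 0.26), Lhx9 (1.00 ± 0.14) and the GABA synthesis enzyme Gad1 (0.97 ± 0.21). Amacrine genes had a median of 0.57, a mean above every control in 4 of 4, camera adjusted p = 2.49e-05 and 0.465 at an estimated correlation. Of retinal ganglion cell genes, 9 of 19 rose, 0 fell and 10 did not pass (12 up, 0 down adjusted over the list alone), including Pou4f1 (0.38 ± 0.04) and the glutamate transporter gene Slc17a6 (0.36 ± 0.07). Retinal ganglion cell genes had a median of 0.21, a mean above every control in 4 of 4, camera adjusted p = 4.05e-05 and 0.48 at an estimated correlation. In the synaptic list 9 of 15 rose, 0 fell and 6 did not pass (12 up, 0 down adjusted over the list alone), led by the vesicle protein genes Sv2a (0.48 ± 0.05), Cplx3 (0.59 ± 0.08) and Syp (0.40 ± 0.07). Synaptic genes had a median of 0.36, a mean above every control in 4 of 4, camera adjusted p = 4.42e-07 and 0.416 at an estimated correlation. Endothelial genes were higher in the same libraries: 2 of 6 rose, 0 fell and 4 did not pass (2 up, 0 down adjusted over the list alone), Cldn5 at 1.86 ± 0.15. Endothelial genes had a median of 0.96, a mean above every control in 2 of 4, camera adjusted p = 0.00703 and 0.465 at an estimated correlation.

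Progenitor, DNA replication and ribosomal protein lists were lower at E17.5. Of the progenitor list 2 of 18 rose, 5 fell and 11 did not pass (2 up, 6 down adjusted over the list alone): Vsx2, a progenitor homeobox gene, fell (-0.31 ± 0.06), as did the Notch effector Hes1 (-0.56 ± 0.10) and cyclin D1, Ccnd1 (-0.31 ± 0.07), while Fgf15 rose (0.41 ± 0.07). Progenitor genes had a median of -0.13, a mean below every control in 4 of 4, camera adjusted p = 0.0221 and 0.416 at an estimated correlation. In the DNA replication list 3 of 22 rose, 12 fell and 7 did not pass (3 up, 13 down adjusted over the list alone), with Mcm6 at -0.36 ± 0.06 and Mcm4 at -0.33 ± 0.06 but cyclin E1, Ccne1, at 0.58 ± 0.11. DNA replication genes had a median of -0.22, a mean below every control in 3 of 4, camera adjusted p = 0.000724 and 0.663 at an estimated correlation. Of replication-dependent histones, 0 of 16 rose, 4 fell and 12 did not pass (0 up, 7 down adjusted over the list alone), the linker histone gene Hist1h1d at -0.25 ± 0.06. Replication-dependent histone genes had a median of -0.10, a mean below every control in 2 of 4, camera adjusted p = 0.00306 and 0.663 at an estimated correlation. Nearly the whole ribosomal protein list moved: 0 of 30 rose, 29 fell and 1 did not pass (0 up, 30 down adjusted over the list alone), for example Rpl5 (-0.41 ± 0.05) and Rps24 (-0.40 ± 0.04). Ribosomal protein genes had a median of -0.28, a mean below every control in 4 of 4, camera adjusted p = 1.93e-28 and 0.416 at an estimated correlation. Of the integrated stress list 1 of 19 rose, 7 fell and 11 did not pass (1 up, 9 down adjusted over the list alone), those that fell including the amino acid response genes Slc7a5 (-0.74 ± 0.09) and Asns (-0.46 ± 0.08). Integrated stress and unfolded protein genes had a median of -0.15, a mean below every control in 3 of 4, camera adjusted p = 0.00842 and 0.598 at an estimated correlation.

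Of p53 targets 7 of 18 rose, 0 fell and 11 did not pass (8 up, 1 down adjusted over the list alone), with the cell cycle inhibitor Cdkn1a at 0.81 ± 0.15 and Trp53inp1 at 0.30 ± 0.05. P53 target genes had a median of 0.14, a mean above every control in 4 of 4, camera adjusted p = 0.0162 and 0.416 at an estimated correlation. The p53 list did not pass without control 2 (adjusted p = 0.0559). For cholesterol synthesis 0 of 18 rose, 4 fell and 14 did not pass (0 up, 5 down adjusted over the list alone), Idi1 at -0.31 ± 0.06. Cholesterol synthesis genes had a median of -0.11, a mean below every control in 3 of 4, camera adjusted p = 0.00465 and 0.663 at an estimated correlation. This call did not pass without control 4 (adjusted p = 0.0555). EdgeR called 2299 of 14086 tested genes at E17.5, 1234 higher and 1065 lower. Of these 99 changed at least 2-fold (83 up, 16 down). An unadjusted p under 0.05 was reached by 4365, and 21.4% had no overlap between groups. The count fell to 1338 without control 2, 1493 without DKO 1 and 1475 without DKO 2, and stood at 1665 without control 4 and DKO 1, which held more haemoglobin counts (Hba-a1 at 69.4 and 96.9 CPM against 7.34 to 34.0 CPM in the other 6). Leaving out both replicate 1 libraries gave 1067. Limma on log2(TPM + 1) called 309 genes, 277 up and 32 down.

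At birth rod genes were again higher, and the hypoxia and glycolysis list was lower. Rhodopsin, Rho (chromosome 6, 115931748 to 115940036), rose from 4.95 ± 1.35 to 26.5 ± 14.1 CPM (2.48 ± 0.35, adjusted p = 0.00375), and the rod channel subunit Cnga1 from 0.332 ± 0.178 to 4.29 ± 2.06 CPM (3.79 ± 0.50, adjusted p = 0.00199). Further rises were the lysosomal membrane gene Lamp5 (3.56 ± 0.52, adjusted p = 0.00391), the ectonucleotidase gene Entpd2 (2.30 ± 0.30, adjusted p = 0.00199) and the calcium-binding protein gene Necab3 (2.42 ± 0.33, adjusted p = 0.00245). Pyruvate dehydrogenase kinase 1, Pdk1 (chromosome 2, 71873224 to 71903858), fell from 122 ± 56.0 to 32.9 ± 4.02 CPM (-1.89 ± 0.32, adjusted p = 0.00707), as did the mitochondrial genes Ndufa4l2 (-1.90 ± 0.30, adjusted p = 0.00445) and Cox4i2 (-1.19 ± 0.21, adjusted p = 0.00745), all 3 of which were low in control 1 too. The glutathione-degrading enzyme gene Chac1 (-1.78 ± 0.36, adjusted p = 0.0115), the translation repressor gene Eif4ebp1 (-1.41 ± 0.26, adjusted p = 0.00865) and the retinoic acid synthesis gene Aldh1a3 (-1.23 ± 0.20, adjusted p = 0.00604) fell. Rpl29 (chromosome 9, 106429454 to 106431568) fell (-1.16 ± 0.06, adjusted p = 3.64e-07) and was still lower with the counts of its near-identical pseudogene copies added (363.1 ± 17.6 to 228.6 ± 14.9 CPM), so the size of its fall is uncertain.

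In the rod list 17 of 22 rose, 0 fell and 5 did not pass (19 up, 0 down adjusted over the list alone), among them Nr2e3 (1.19 ± 0.12), Nrl (0.98 ± 0.11) and the outer segment gene Rom1 (0.93 ± 0.12). Rod genes had a median of 1.01, a mean above every control in 4 of 4, camera adjusted p = 3.04e-19 and 0.367 at an estimated correlation. Of amacrine genes, 9 of 12 rose, 0 fell and 3 did not pass (10 up, 1 down adjusted over the list alone), for example Lhx9 (0.46 ± 0.07), the glycine transporter gene Slc6a9 (0.79 ± 0.13) and Npy (0.97 ± 0.19). Amacrine cell genes had a median of 0.51, a mean above every control in 4 of 4, camera adjusted p = 1.71e-06 and 0.367 at an estimated correlation. Of the synaptic list 5 of 15 rose, 0 fell and 10 did not pass (6 up, 0 down adjusted over the list alone), including Cplx3 (0.68 ± 0.10) and the vesicular glutamate transporter Slc17a7 (1.15 ± 0.21). Synaptic genes had a median of 0.25, a mean above every control in 4 of 4, camera adjusted p = 0.00014 and 0.373 at an estimated correlation. For endothelial genes 5 of 12 rose, 0 fell and 7 did not pass (7 up, 0 down adjusted over the list alone), led by Cldn5 (1.59 ± 0.21) and the angiopoietin receptor family gene Tie1 (1.80 ± 0.34). Endothelial genes had a median of 1.32, a mean above every control in 3 of 4, camera adjusted p = 0.000499 and 0.451 at an estimated correlation. On log2(TPM + 1) the median was 0.18, and 0.13 over all genes. Of microglia and macrophage genes, 4 of 11 rose, 0 fell and 7 did not pass (8 up, 0 down adjusted over the list alone). Microglia and macrophage genes had a median of 0.62, a mean above every control in 4 of 4, camera adjusted p = 0.00276 and 0.396 at an estimated correlation. Of the pigment epithelium list 3 of 7 rose, 0 fell and 4 did not pass (5 up, 0 down adjusted over the list alone). Pigment epithelium genes had a median of 0.69, a mean above every control in 4 of 4, camera adjusted p = 0.0026 and 0.373 at an estimated correlation. For the astrocyte list 0 of 4 rose, 0 fell and 4 did not pass (3 up, 0 down adjusted over the list alone). Astrocyte genes had a median of 0.76, a mean above every control in 3 of 4, camera adjusted p = 0.0448 and 0.451 at an estimated correlation. The astrocyte list did not pass without control 1 (adjusted p = 0.15), the library labelled control 2 (adjusted p = 0.0665), DKO 1 (adjusted p = 0.0784), DKO 3 (adjusted p = 0.0532) or DKO 4 (adjusted p = 0.0725).

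Among hypoxia and glycolysis genes, 4 of 21 rose, 10 fell and 7 did not pass (4 up, 10 down adjusted over the list alone). Phosphofructokinase Pfkl (-1.16 ± 0.18) and enolase Eno1 (-0.95 ± 0.16) fell, whereas the stress-induced mTOR inhibitor Ddit4 rose (0.62 ± 0.10). This list had a median of -0.15, a mean below every control in 2 of 4, camera adjusted p = 0.0438 and 0.483 at an estimated correlation. The glycolysis list did not pass without control 4 (adjusted p = 0.0674), DKO 2 (adjusted p = 0.124) or DKO 4 (adjusted p = 0.096). In the integrated stress list 0 of 19 rose, 9 fell and 10 did not pass (1 up, 11 down adjusted over the list alone), including Atf5 (-0.64 ± 0.10) and Slc7a5 (-1.12 ± 0.20). Integrated stress and unfolded protein genes had a median of -0.43, a mean below every control in 4 of 4, camera adjusted p = 4.98e-05 and 0.373 at an estimated correlation. Of mitochondrially encoded genes, 0 of 13 rose, 6 fell and 7 did not pass (0 up, 9 down adjusted over the list alone). Mitochondrially encoded genes had a median of -0.30, a mean below every control in 4 of 4, camera adjusted p = 1.54e-05 and 0.367 at an estimated correlation. Of the ribosomal protein list 0 of 30 rose, 28 fell and 2 did not pass (0 up, 30 down adjusted over the list alone), for example Rps16 (-0.55 ± 0.08) and Rps20 (-0.48 ± 0.09). Ribosomal protein genes had a median of -0.35, a mean below every control in 4 of 4, camera adjusted p = 1.05e-21 and 0.373 at an estimated correlation.

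Lists of DNA replication, FGF feedback and progenitors were lower. For DNA replication 0 of 22 rose, 14 fell and 8 did not pass (0 up, 16 down adjusted over the list alone), with Gins2 at -0.63 ± 0.11 and Mcm4 at -0.46 ± 0.09. DNA replication genes had a median of -0.34, a mean below every control in 3 of 4, camera adjusted p = 1.1e-09 and 0.373 at an estimated correlation. Of replication-dependent histones, 0 of 16 rose, 3 fell and 13 did not pass (0 up, 7 down adjusted over the list alone). Replication-dependent histone genes had a median of -0.19, a mean below every control in 3 of 4, camera adjusted p = 3.26e-05 and 0.451 at an estimated correlation. In the FGF and MAPK feedback list 2 of 14 rose, 5 fell and 7 did not pass (2 up, 7 down adjusted over the list alone), the ERK phosphatase gene Dusp6 (-0.62 ± 0.09) and the ETS factor Etv5 (-0.52 ± 0.09) falling. FGF and MAPK feedback genes had a median of -0.24, a mean below every control in 4 of 4, camera adjusted p = 0.0304 and 0.367 at an estimated correlation. The feedback list did not pass without control 1 (adjusted p = 0.0637). Of progenitor genes, 2 of 18 rose, 3 fell and 13 did not pass (2 up, 6 down adjusted over the list alone). Retinal progenitor genes had a median of -0.17, a mean below every control in 3 of 4, camera adjusted p = 0.0162 and 0.451 at an estimated correlation. The progenitor list did not pass without control 1 (adjusted p = 0.0676) or DKO 3 (adjusted p = 0.0532).

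EdgeR called 1350 of 13914 tested genes at P0, 650 higher and 700 lower. At least 2-fold changes numbered 148 (113 up, 35 down). For 3888 genes the unadjusted p was under 0.05, and 14.8% had no overlap between groups. Single libraries moved this count widely: 2665 without control 1, 493 without the library labelled control 2, 555 without control 3, 596 without control 4, 407 without DKO 3 and 258 without DKO 4. Limma on log2(TPM + 1) called 861 genes, 791 up and 70 down.

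At P5, when bipolar cells form, bipolar cell genes rose in the DKO group. The glutamate receptor Grm6, which receives photoreceptor input (chromosome 11, 50850685 to 50866208), went from 1.04 ± 0.928 to 10.1 ± 4.95 CPM (3.41 ± 0.59, adjusted p = 0.0212), the calcium sensor gene Scgn from 1.68 ± 0.936 to 14.9 ± 6.32 CPM (3.22 ± 0.44, adjusted p = 0.00978), and the GABA receptor subunit gene Gabrr1 (chromosome 4, 33132521 to 33163588) from 1.49 ± 0.634 to 14.0 ± 4.91 CPM (3.30 ± 0.36, adjusted p = 0.00298). Serpine3, a serpin family member, rose (3.76 ± 0.41, adjusted p = 0.00298), and the secreted glycoprotein gene Spp1 (2.96 ± 0.57, adjusted p = 0.0336) and the lens crystallin gene Crybb1 (2.23 ± 0.45, adjusted p = 0.042) were also higher. The lactate transporter Slc16a3 (chromosome 11, 120948480 to 120960868) fell from 57.0 ± 8.20 to 24.7 ± 3.54 CPM (-1.22 ± 0.13, adjusted p = 0.00298). Falls were also called for the intermediate filament gene Nes (-1.39 ± 0.20, adjusted p = 0.0102), Dusp16 (-1.08 ± 0.18, adjusted p = 0.0168) and the cone transducin subunit Gngt2 (-0.97 ± 0.15, adjusted p = 0.0145). Crybb1 stood at 12.1 CPM in the library labelled DKO 1 and at 3.40 to 4.86 CPM in the other DKO libraries. The call was lost in a refit of 7 libraries for Grm6 (adjusted p = 0.0929 without control 1), Spp1 (adjusted p = 0.106 without control 2), Crybb1 (adjusted p = 0.12 without control 2), Nes (adjusted p = 0.0505 without the library labelled DKO 3), Dusp16 (adjusted p = 0.0704 without the library labelled DKO 3) and Gngt2 (adjusted p = 0.0597 without the library labelled DKO 3).

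In the bipolar list 7 of 18 rose, 0 fell and 11 did not pass (13 up, 0 down adjusted over the list alone). Besides Scgn they included the transduction channel Trpm1 (2.01 ± 0.27). Bipolar genes had a median of 0.91, a mean above every control in 4 of 4, camera adjusted p = 2.11e-12 and 0.262 at an estimated correlation. Of hypoxia and glycolysis genes, 0 of 21 rose, 9 fell and 12 did not pass (0 up, 17 down adjusted over the list alone), among them hexokinase 2, Hk2 (-0.85 ± 0.11), and the mitophagy receptor Bnip3 (-0.87 ± 0.12). Hypoxia and glycolysis genes had a median of -0.43, a mean below every control in 4 of 4, camera adjusted p = 6.96e-18 and 0.2 at an estimated correlation. For microglia and macrophages 5 of 17 rose, 0 fell and 12 did not pass (15 up, 0 down adjusted over the list alone). Microglia and macrophage genes had a median of 0.84, a mean above every control in 4 of 4, camera adjusted p = 1.33e-12 and 0.254 at an estimated correlation. Of the reactive glia list 1 of 9 rose, 0 fell and 8 did not pass (4 up, 0 down adjusted over the list alone), the riser being the filament gene Gfap (1.32 ± 0.14). Reactive glia genes had a median of 0.27, a mean above every control in 4 of 4, camera adjusted p = 0.00133 and 0.2 at an estimated correlation. Of astrocyte genes, 2 of 6 rose, 0 fell and 4 did not pass (4 up, 0 down adjusted over the list alone). Astrocyte genes had a median of 0.72, a mean above every control in 4 of 4, camera adjusted p = 4.78e-05 and 0.262 at an estimated correlation. For Muller glia 2 of 18 rose, 1 fell and 15 did not pass (6 up, 2 down adjusted over the list alone). Muller glia genes had a median of 0.15, a mean above every control in 4 of 4, camera adjusted p = 0.0106 and 0.262 at an estimated correlation. Of horizontal cell genes, 1 of 8 rose, 0 fell and 7 did not pass (2 up, 0 down adjusted over the list alone), the homeobox gene Prox1 being the riser (0.84 ± 0.10). Horizontal cell genes had a median of 0.36, a mean above every control in 3 of 4, camera adjusted p = 0.00601 and 0.489 at an estimated correlation. In the cone list 0 of 13 rose, 2 fell and 11 did not pass (0 up, 2 down adjusted over the list alone). Cone genes had a median of -0.26, a mean below every control in 1 of 4, camera adjusted p = 0.000136 and 0.489 at an estimated correlation.

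Of ribosomal protein genes, 0 of 30 rose, 1 fell and 29 did not pass (0 up, 17 down adjusted over the list alone) at P5. Ribosomal protein genes had a median of -0.19, a mean below every control in 4 of 4, camera adjusted p = 5.3e-13 and 0.398 at an estimated correlation. In the list of hedgehog, Wnt and BMP targets 1 of 14 rose, 0 fell and 13 did not pass (9 up, 1 down adjusted over the list alone), the BMP target Id3 being the riser (0.45 ± 0.09). Hedgehog, Wnt and BMP target genes had a median of 0.42, a mean above every control in 4 of 4, camera adjusted p = 0.00232 and 0.2 at an estimated correlation. Of the pigment epithelium list 1 of 11 rose, 0 fell and 10 did not pass (7 up, 0 down adjusted over the list alone), Gpnmb being the riser (1.53 ± 0.25). Pigment epithelium genes had a median of 0.57, a mean above every control in 3 of 4, camera adjusted p = 1.03e-05 and 0.318 at an estimated correlation. Of lens genes, 1 of 6 rose, 0 fell and 5 did not pass (3 up, 0 down adjusted over the list alone). Lens genes had a median of 1.62, a mean above every control in 4 of 4, camera adjusted p = 0.00339 and 0.489 at an estimated correlation. This call was lost without the libraries labelled DKO 1 and DKO 3 (adjusted p = 0.0793). Of endothelial genes, 0 of 16 rose, 0 fell and 16 did not pass (0 up, 0 down adjusted over the list alone). Endothelial genes had a median of 0.30, a mean above every control in 0 of 4, camera adjusted p = 0.00296 and 0.489 at an estimated correlation. For cholesterol synthesis 0 of 19 rose, 0 fell and 19 did not pass (0 up, 5 down adjusted over the list alone). Cholesterol synthesis genes had a median of -0.10, a mean below every control in 2 of 4, camera adjusted p = 0.00118 and 0.571 at an estimated correlation. On log2(TPM + 1) the median was 0.06, and 0.13 over all genes. Of the synaptic list 0 of 15 rose, 0 fell and 15 did not pass (1 up, 0 down adjusted over the list alone). Synaptic genes had a median of 0.13, a mean above every control in 1 of 4, camera adjusted p = 0.0468 and 0.663 at an estimated correlation. The synaptic list did not pass without control 4 (adjusted p = 0.728), the library labelled DKO 3 (adjusted p = 0.0501) or DKO 4 (adjusted p = 0.18). Not every call held in refits of 7 libraries: Id3 (adjusted p = 0.156 without the library labelled DKO 3) and Gpnmb (adjusted p = 0.0664 without the library labelled DKO 3).

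EdgeR called 208 of 14168 tested genes at P5, 129 higher and 79 lower. Of the calls 65 reached 2-fold (52 up, 13 down). Unadjusted, 2389 genes had p under 0.05, and 10% had no overlap between groups. The count was 54 without control 1, 88 without control 2, 844 without control 3, 125 without the library labelled DKO 1, 72 without DKO 2, 50 without the library labelled DKO 3 and 62 without DKO 4. It was 15 without both libraries labelled DKO 1 and DKO 3, 65 with the replicate number as a block, and on the log2(TPM + 1) scale limma called 34 genes, 30 up and 4 down.

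At P16 genes of reactive glia and of immune cells rose. Gfap, the filament protein of reactive Muller glia and astrocytes (chromosome 11, 102887336 to 102900912), rose from 18.9 ± 11.9 to 186 ± 79.8 CPM (3.31 ± 0.46, adjusted p = 0.00601). Complement component 4, C4b (chromosome 17, 34728380 to 34743882), went from 1.36 ± 1.17 to 56.9 ± 34.7 CPM (5.42 ± 0.68, adjusted p = 0.00548), the serpin Serpina3n rose (3.23 ± 0.39, adjusted p = 0.00489), and the transcription factor Cebpd rose (2.68 ± 0.42, adjusted p = 0.00719) with the collagen-processing gene Pcolce (3.10 ± 0.53, adjusted p = 0.00824). Endothelin 2, Edn2, had 1 count over the 4 controls and 223 over the DKO libraries, a ratio of 230.0 (95% interval 40.8 to 9110.0), and Glycam1 had 4 and 322, a ratio of 82.9 (32.1 to 306), both intervals covering counting error only. DKO 1 stood apart for Gfap, at 66.9 CPM against 217 to 233 CPM in the other 3, and control 1 at 36.5 CPM against 10.8 to 14.9 CPM. Genes that fell included Wfikkn2, which encodes a protease inhibitor domain protein (-1.14 ± 0.21, adjusted p = 0.012), Fsbp (-1.13 ± 0.15, adjusted p = 0.00548) and Rpl29 (-1.02 ± 0.13, adjusted p = 0.00548), the last again lower with its copies added (119.2 ± 3.41 to 80.99 ± 16.1 CPM).

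In the reactive glia list 14 of 15 rose, 0 fell and 1 did not pass (14 up, 0 down adjusted over the list alone), with the protease inhibitor A2m at 1.68 ± 0.20. This list had a median of 1.68, a mean above every control in 4 of 4, camera adjusted p = 6.66e-11 and 0.472 at an estimated correlation. For microglia and macrophages 15 of 18 rose, 0 fell and 3 did not pass (16 up, 0 down adjusted over the list alone), among them the signalling adaptor Tyrobp (1.89 ± 0.32), complement C1qb (1.41 ± 0.23) and Ly86 (0.95 ± 0.17). Microglia and macrophage genes had a median of 1.11, a mean above every control in 4 of 4, camera adjusted p = 6.14e-08 and 0.472 at an estimated correlation. Of interferon response genes, 8 of 16 rose, 0 fell and 8 did not pass (12 up, 0 down adjusted over the list alone), led by the GTPase Gbp2 (1.76 ± 0.24). Interferon response genes had a median of 0.84, a mean above every control in 4 of 4, camera adjusted p = 1.75e-05 and 0.472 at an estimated correlation. Of the integrated stress list 6 of 21 rose, 0 fell and 15 did not pass (9 up, 0 down adjusted over the list alone), including the stress-induced factors Atf3 (1.45 ± 0.23) and Cebpb (1.49 ± 0.24). Integrated stress and unfolded protein genes had a median of 0.26, a mean above every control in 4 of 4, camera adjusted p = 0.000722 and 0.472 at an estimated correlation. Of FGF and MAPK feedback genes, 3 of 13 rose, 0 fell and 10 did not pass (7 up, 2 down adjusted over the list alone). FGF and MAPK feedback genes had a median of 0.44, a mean above every control in 4 of 4, camera adjusted p = 0.0235 and 0.472 at an estimated correlation. Of the erythroid list 0 of 5 rose, 0 fell and 5 did not pass (5 up, 0 down adjusted over the list alone). Erythroid genes had a median of 0.89, a mean above every control in 3 of 4, camera adjusted p = 0.0399 and 0.524 at an estimated correlation. The erythroid list did not pass without control 3 (adjusted p = 0.0733), control 4 (adjusted p = 0.09), DKO 1 (adjusted p = 0.116), DKO 2 (adjusted p = 0.0885) or DKO 3 (adjusted p = 0.071). Of the ciliary margin list 2 of 8 rose, 0 fell and 6 did not pass (2 up, 0 down adjusted over the list alone), Zic1 at 1.56 ± 0.28. Ciliary margin genes had a median of 0.72, a mean above every control in 3 of 4, camera adjusted p = 0.0399 and 0.524 at an estimated correlation. The ciliary margin list did not pass without DKO 3 (adjusted p = 0.0523) or DKO 4 (adjusted p = 0.142).

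Photoreceptor lists were lower at P16 than the other genes. For rods 0 of 24 rose, 0 fell and 24 did not pass (0 up, 0 down adjusted over the list alone), yet its test passed. Rod genes had a median of -0.69, a mean below every control in 3 of 4, camera adjusted p = 6.14e-08 and 0.513 at an estimated correlation. The mean of DKO 1 lay above every control and the other 3 DKO libraries below. Of the cone list 0 of 14 rose, 5 fell and 9 did not pass (1 up, 9 down adjusted over the list alone). Cone genes had a median of -0.39, a mean below every control in 3 of 4, camera adjusted p = 9.38e-05 and 0.472 at an estimated correlation. Ganglion and amacrine lists were higher, bipolar and horizontal not called. Of the first, 7 of 19 rose, 0 fell and 12 did not pass (9 up, 0 down adjusted over the list alone). Slc17a6 was at 0.41 ± 0.07 and Ebf3 at 0.53 ± 0.09. The list had a median of 0.30 and a mean above every control in 3 of 4. Camera adjusted p was 0.000519, and 0.508 at an estimated correlation. Of amacrine genes, 4 of 15 rose, 0 fell and 11 did not pass (8 up, 0 down adjusted over the list alone). They had a median of 0.35 and a mean above every control in 3 of 4. Camera adjusted p was 0.00053, and 0.472 at an estimated correlation. In the synaptic list 7 of 15 rose, 0 fell and 8 did not pass (8 up, 1 down adjusted over the list alone), among them the active zone genes Bsn (1.24 ± 0.18) and Pclo (1.47 ± 0.22) and the vesicle protein Syn1 (1.27 ± 0.18). Synaptic genes had a median of 0.24, a mean above every control in 4 of 4, camera adjusted p = 0.00364 and 0.472 at an estimated correlation. Of mitochondrially encoded genes, 5 of 12 rose, 0 fell and 7 did not pass (8 up, 0 down adjusted over the list alone). Mitochondrially encoded genes had a median of 0.50, a mean above every control in 3 of 4, camera adjusted p = 0.000285 and 0.472 at an estimated correlation. For pigment epithelium 1 of 13 rose, 0 fell and 12 did not pass (1 up, 3 down adjusted over the list alone), Gpnmb, also made by macrophages, being the riser (1.41 ± 0.25). Pigment epithelium genes had a median of -1.02, a mean below every control in 3 of 4, camera adjusted p = 0.00686 and 0.524 at an estimated correlation. Of ribosomal protein genes, 0 of 30 rose, 3 fell and 27 did not pass (0 up, 16 down adjusted over the list alone). Ribosomal protein genes had a median of -0.30, a mean below every control in 3 of 4, camera adjusted p = 7.41e-10 and 0.508 at an estimated correlation.

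**Figure D2:**
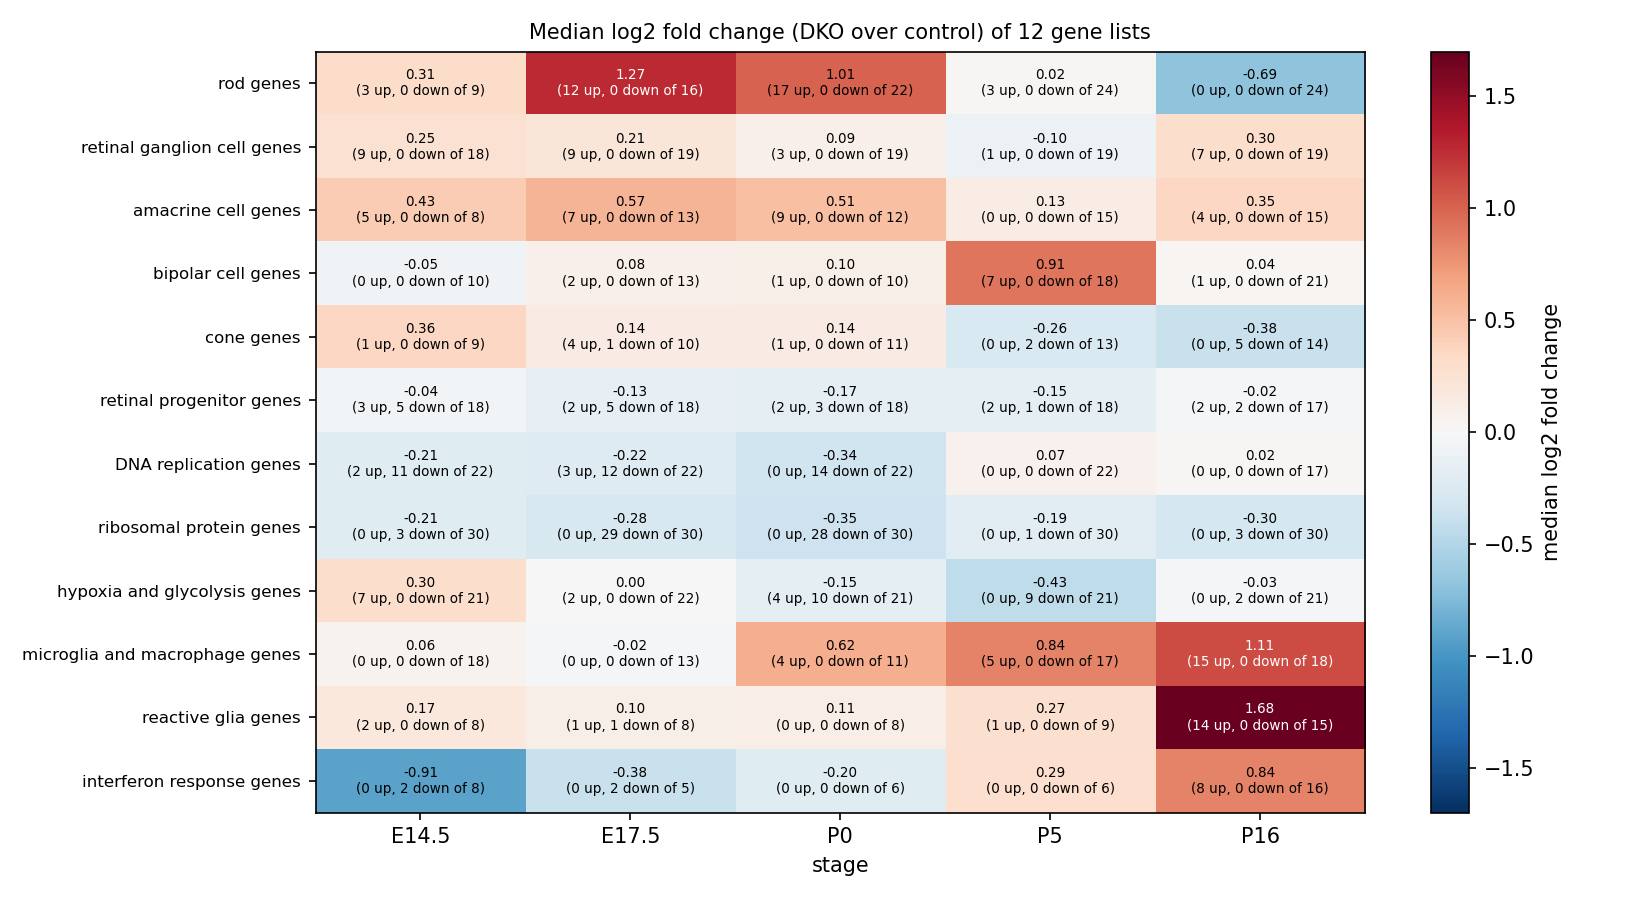
Median log2 fold change of DKO over control for 12 gene lists (rows) at the 5 stages (columns), with the numbers of members called up and down and tested in each cell. The rod list has medians of 1.27 at E17.5, 1.01 at P0 and -0.69 at P16, and the reactive glia list 1.68 at P16; the median of the ribosomal protein list is below 0 at every stage.

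EdgeR called 1732 of 14301 tested genes at P16, 1229 higher and 503 lower. A change of 2-fold or more was called for 272 (233 up, 39 down). Without adjustment 4503 genes had p under 0.05, and 16.9% had no overlap between groups. The share of higher calls was 71.0%, and 60.5% with each library's trend over gene length removed. On the log2(TPM + 1) scale, where the median of all genes moved by 0.16, limma called 23 genes, 21 up and 2 down. Without DKO 1, with few Gm36660 counts, 5150 genes were called. The count was 816 without control 1, 481 without control 2, 405 without control 3, 505 without control 4, 615 without DKO 2, 458 without DKO 3 and 1129 without DKO 4.

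The difference between consecutive stages in the DKO effect was tested as an interaction. Between P0 and P5 the effect on 2 rod genes dropped: Nrl went from 0.98 to -0.30 (difference -1.273 ± 0.17, adjusted p = 0.00281) and Nr2e3 from 1.19 to -0.38 (difference -1.568 ± 0.19, adjusted p = 0.00165). The paired-box gene Pax7 showed the largest drop, from 3.56 to -0.80 (difference -4.359 ± 0.53, adjusted p = 0.00165). The effect on Prox1 rose, from -0.10 to 0.84 (difference 0.939 ± 0.13, adjusted p = 0.00351), as did that on the splicing factor gene Hnrnpa3, from -0.47 to 0.43 (difference 0.898 ± 0.12, adjusted p = 0.00284). From P5 to P16 the effect on 3 bipolar genes dropped, Scgn going from 3.22 to 0.11 (difference -3.11 ± 0.40, adjusted p = 0.00217), Trpm1 from 2.01 to 0.10 (difference -1.891 ± 0.27, adjusted p = 0.00422) and Gabrr1 from 3.30 to -0.03 (difference -3.344 ± 0.33, adjusted p = 0.000228). Bnip3 went the other way, from -0.87 to 0.23 (difference 1.097 ± 0.15, adjusted p = 0.00235). Between E14.5 and E17.5 the effect on Fgf15 fell from 1.39 to 0.41 (difference -0.977 ± 0.13, adjusted p = 0.00323), while that on the mTORC2 partner gene Prr5l rose from -0.47 to 0.51 (difference 0.987 ± 0.13, adjusted p = 0.00323).

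EdgeR called 22 genes with a different effect at E17.5 than at E14.5 (4 with a higher effect later, 18 lower). This count was 13 without E14.5 control 1, 12 without E14.5 DKO 2, 12 without E17.5 control 1, 8 without E17.5 control 2, 7 without E17.5 DKO 2 and 4 without both E17.5 replicate 1 libraries. For P0 against E17.5 edgeR called 0 genes, with 1575 at an unadjusted p under 0.05 and 31 called by DESeq2. Without P0 control 1 this became 425, without P0 DKO 2 it was 2, and without E17.5 DKO 3 or DKO 4 it was 1. For P5 against P0 it called 336 genes (131 higher, 205 lower). Leaving out P0 libraries gave 1109 without control 1, 166 without the library labelled control 2, 163 without control 3, 193 without control 4, 172 without DKO 3 and 143 without DKO 4. Leaving out P5 libraries gave 191 without control 1, 204 without control 2, 557 without control 3, 859 without control 4 and 204 without the library labelled DKO 3. Without the libraries labelled P0 control 2, P5 DKO 1 and P5 DKO 3, 5 genes were called. For P16 against P5, 332 genes were called (210 higher, 122 lower). That count was 185 without P5 control 1, 181 without P5 control 2, 199 without the library labelled P5 DKO 1, 117 without P5 DKO 2, 177 without the library labelled P5 DKO 3 and 133 without P5 DKO 4. It was 214, 115, 125 and 136 without P16 controls 1 to 4, 1637 without P16 DKO 1, 144 without P16 DKO 2 and 125 without P16 DKO 3.

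Of 12658 genes tested at all 5 stages, 7981 were called at 0 stages, 3042 at 1, 1233 at 2, 360 at 3, 37 at 4 and 5 at all 5. A set of 4 genes changed in 1 direction throughout: Gm36660, Abcd4 and Cntnap2 rose and Rplp2 fell. Abcd4 (chromosome 12, 84601464 to 84617413) lies beside Vsx2 and may mark the transgene. Its log2 fold changes were 2.09, 2.22, 2.76, 2.25 and 2.03 from E14.5 to P16 (highest adjusted p = 0.000492). Cntnap2, a neurexin family adhesion gene (chromosome 6, 45059357 to 47304213), rose by 0.56, 0.29, 0.43, 0.81 and 0.57 (highest adjusted p = 0.043). Rplp2, a ribosomal stalk protein gene (chromosome 7, 141447370 to 141451585), fell by 0.28, 0.29, 0.40, 0.27 and 0.37 (highest adjusted p = 0.0482). E14.5 and E17.5 shared 457 higher and 347 lower calls, with 5 opposite, where independent lists would give 87.4, 66.6 and 152.7. E17.5 and P0 shared 307 higher and 365 lower, against 55.0 and 54.3. P5 and P16 shared 35 higher and 5 lower, against 10.5 and 2.70, and E14.5 and P16 shared 124 higher, 42 lower and 82 opposite, against 82.1, 28.9 and 102.3. P0 and P16 shared 107 higher, 20 lower and 62 opposite, against 53.2, 23.5 and 77.8, and E14.5 and P5 shared 22, 7 and 14, against 7.80, 4.70 and 12.1. No library is shared between stages.

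Transcripts carrying the ZFP36 binding motif UAUUUAU in the 3' UTR were compared with transcripts that lack it. For each library the score was the mean log2 CPM of genes with 2 or more motifs minus that of genes with 0, matched on 3' UTR length and expression. Over 1392 pairs at E14.5 the score was -0.06 ± 0.03 in controls and 0.05 ± 0.03 in DKO libraries (SD, n = 4), a difference of 0.11, or 1.08-fold (exact two-sided permutation p = 0.0286, the smallest 4 against 4 can give, adjusted p = 0.0715 over the 5 stages). At E17.5 it was -0.03 ± 0.01 against 0.03 ± 0.02, a difference of 0.06 (exact permutation p = 0.0286, adjusted p = 0.0715). At both stages the score of 4 of 4 DKO libraries lay above every control. The differences were 0.03 at P0 (exact permutation p = 0.0857), 0.02 at P5 (exact permutation p = 0.229) and 0.00 at P16 (exact permutation p = 0.943). With the adjustment over 5 stages no stage passed, and neither did any difference between consecutive stages (smallest permutation p = 0.192, P16 against P5).

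**Figure D3:**
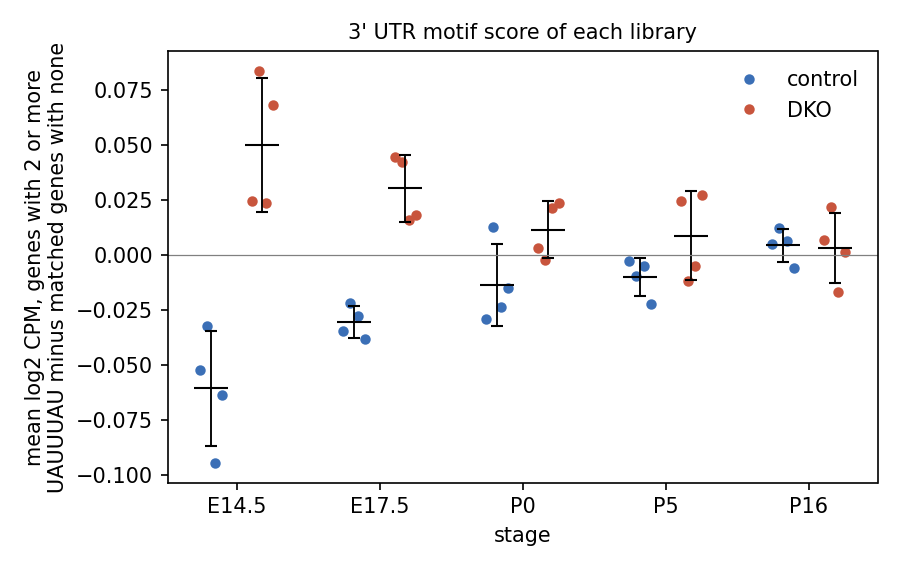
Score of 3' UTR motif genes in each library, as the mean log2 CPM of genes with 2 or more UAUUUAU minus matched genes with 0, by stage, with points for libraries and bars for mean ± SD of 4. At E14.5 and E17.5 every DKO library lies above every control, with differences of 0.11 and 0.06.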

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

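The tests of Gm36660, of the chromosome 9 window and of ribosomal protein genes were chosen after the values they address were seen.

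Among 206 groups of 4 libraries, 15 held a value whose gap exceeded the critical value of Dixon's test, where chance gives 1 in 20. At E14.5 these were Zfp36l2 in DKO 4 (6.156 CPM against 13.4 to 14.2), Hba-x in control 3 (3.407 against 1.73 to 1.94), and Igtp (14.92 against 1.53 to 2.70) and Ctsh (4.253 against 2.04 to 2.35) in control 4. At E17.5 Samd4 stood at 12.06 CPM in control 4 (others 8.19 to 8.81). P0 control 1 was low for the hypoxia genes Ndufa4l2 (52.79 against 137 to 144), Pdk1 (38.12 against 145 to 156) and Cox4i2 (24.15 against 48.9 to 53.7). At P5 the values were Zfp36l1 in control 4 (37.83 against 27.8 to 29.3), Crybb1 in the library labelled DKO 1 (12.07 against 3.40 to 4.86) and C2cd4b in control 3 (5.585 against 8.05 to 8.17). At P16 they were Edn2 in control 1 (0.1089 against 0), Gfap in control 1 (36.49 against 10.8 to 14.9) and in DKO 1 (66.86 against 217 to 233), and Rasl11a in DKO 1 (7.321 against 2.19 to 3.06).

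The DKO effect differed between stages for 22 genes (E17.5 against E14.5), 336 genes (P5 against P0) and 332 genes (P16 against P5). The differences of log2 fold changes from E14.5 to E17.5 were 0.987 for Prr5l, -0.977 for Fgf15, -0.907 for Atf5, -0.462 for Pdia6, -0.58 for Sstr2, -0.702 for Thrb, -0.603 for Tgfb2 and -0.781 for Fgf3. From P0 to P5 they were -4.359 for Pax7, -1.568 for Nr2e3, -1.273 for Nrl, -1.516 for Slc16a3, 0.898 for Hnrnpa3, 0.939 for Prox1, -1.345 for Pcdh15 and -1.205 for Cacna2d4. From P5 to P16 they were -3.344 for Gabrr1, -1.263 for Gsta4, -3.11 for Scgn, 1.268 for Cacna1h, -2.334 for Cltrn, 1.097 for Bnip3, -1.891 for Trpm1 and -1.418 for Cav1.

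Each grouping of 8 libraries into 4 and 4 was tested in turn. The real one called the most genes at every stage (1 of 35): 1913 against a highest other of 4 at E14.5, 2299 against 2, 1350 against 5, 208 against 43 and 1732 against 5 at P16. No other grouping of these libraries reached such gene counts. A place of 1 of 35 is the smallest share this test can give. It was not adjusted over the stages and takes the libraries as exchangeable. List counts were reached by other groupings, so chance cannot be excluded for them. As many lists were called by 3 of 35 groupings at E14.5 (15, highest other 16), 8 at E17.5 (12, highest other 16), 4 at P0 (15, highest other 18), 14 at P5 (15, highest other 19) and 3 at P16 (15, highest other 16). Over 60 drawn regroupings the interaction counts of 336 and 332 stood above the highest others of 26 and 63 (1 of 60 each), while 22 was reached by 3 of 60 (highest other 49) and 0 by 60 of 60 (highest other 15).

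Gm36660 counts in DKO libraries could come from transcription running on past the recombined Zfp36l1 allele. Unspliced reads would also fall on Gm47752, which lies between, but with 0 counts in all libraries it gives no ratio, so this cannot be told apart. A strain haplotype cannot be told apart either: 0 of 19 tested neighbours within 1 Mb were called at 3 or more stages, but at the 3.18% of all genes so called, 0 has a chance of 0.542, so the criterion set beforehand was too weak. From E14.5 to P5 the lowest DKO library held 297 times the control mean (from 2 to 13 counts). This argues against different cell makeup, barring DKO-only cells. At P16 it cannot be told apart: DKO 1 held 25.4 times (pooled ratio 451.5, 95% interval 125 to 3730, counting error only). A spliced fusion transcript was not tested and needs the reads.

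Counts moved between chromosome 9 genes and pseudogene copies: at P0 Rpl29 went from 363 to 162 CPM and its copies from 0.251 to 66.6. Misassigned reads might explain this: for Cyb5r4 the log2 sum of parent and copies moved at most 0.255, with its copy 1.61 to 3.72 higher. But it moved up to 0.471 for Tma7 (P16) and 0.668 for Rpl29, so this cannot tell. Rpl29 copy Gm13841 overlapped only at P5 and E17.5 (controls 0 to 22.2, DKO 0 to 33.5 CPM). A linked chromosome 9 haplotype stays open, as other windows were not tested. At 80 to 115 Mb, 16.97% of 218 genes were called in 1 direction at 2 or more stages. Others gave 11.12% of 12436 (ratio 1.53, Fisher p = 0.00921 if genes are independent).

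Of 30 ribosomal protein genes 3, 29, 28, 1 and 3 fell from E14.5 to P16. Camera called the list at all stages, and at 0 with an estimated correlation (adjusted p = 0.373 to 0.508). This could be technical. With the gene length trend removed the median nearest 0 went from -0.192 to -0.133 (P5), so length bias stays open. Counts on a few abundant genes cannot be told apart: scaling without the top 100 left -0.201, but moved no median by more than 0.009. Nor can a smaller share of dividing progenitors: the lower of the DNA replication and mitosis medians reached at most -0.035 (P5), while mitosis was at 0.04 and 0.06 at E14.5 and E17.5 and replication at 0.07 and 0.03 at P5 and P16.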

How the results depend on the processing

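Removal of the gene length trend and the fits without libraries in doubt were chosen after the data were seen, the other settings before. The cause of any shift below was not tested.

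Limma called 47, 309, 861, 34 and 23 genes from E14.5 to P16 on log2(TPM + 1), and 66, 324, 38 and 33 at E14.5, E17.5, P5 and P16 on log2(TPM + 0.1). An effect of 1.5-fold or more was called for 17, 16, 22, 6 and 13 genes. A single fit of 40 libraries called 1015 at E17.5, 730 at P5 and 3393 at P16. At P5 DESeq2 called 512 and edgeR without a low-count filter 389. With the replicate block 767 genes were called at P0 and 65 at P5. Leaving out both E17.5 libraries numbered 1 gave 1067. Without the libraries in doubt the counts were 493 at P0, 15 at P5 and 5150 at P16.

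With 1 library left out the gene count ranged from 913 to 2061 at E14.5, 1338 to 2143 at E17.5, 258 to 2665 at P0, 50 to 844 at P5 and 405 to 5150 at P16. The lowest came without DKO 4 at E14.5, control 2 at E17.5, DKO 4 at P0, the library labelled DKO 3 at P5 and control 3 at P16, and the highest at P0, P5 and P16 without control 1, control 3 and DKO 1.

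Of 72 list calls, 0 were left with an estimated correlation, at each stage. Fry called 7 lists at E17.5 and 3 at P16. With the length trend removed mural and fibroblast genes at E14.5 (adjusted p = 0.055) and synaptic genes, P5 (0.0539) were lost. Without the libraries in doubt, cholesterol synthesis at E17.5 (0.189), astrocytes at P0 (0.0665), lens at P5 (0.0793) and erythroid genes at P16 (0.116) were lost. On log2(TPM + 1), medians of called lists under 0.5 times as far from the all-gene median included 0.39 for ciliary margin and 0.32 for FGF feedback genes at P16 (all genes 0.16), and for endothelial genes 0.52 at E17.5 (all genes 0.04) and 0.27 at P5 (all genes 0.13). mt-Atp8 at P0 turned from -0.28 to 0.034 with the length trend removed.

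For E17.5 against E14.5, the genes with a different effect numbered 120 with DESeq2, 78 without a filter, 35 without the libraries in doubt, 4 without both E17.5 libraries numbered 1 and 7 to 28 with 1 library left out. For P0 against E17.5 they numbered 31 with DESeq2, 68 without a filter and 0 to 425 with 1 library left out. For P5 against P0 they numbered 687 with DESeq2, 511 without a filter, 5 without the libraries in doubt and 143 to 1109 with 1 library left out. For P16 against P5 they numbered 656 with DESeq2, 1042 without the libraries in doubt and 115 to 1637 with 1 library left out. With the replicate block within each stage the 4 counts were 14, 1, 189 and 154.

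With median-of-ratios factors 1 of the 3 Zfp36 family genes changed over the control stages, and with DESeq2 11 genes were shared by all stages. For the 3' UTR motif score, the sign-flip of same-numbered pairs (replicate block) left 0.1106 at E14.5 and 0.0609 at E17.5 with an exact p = 0.125, the smallest it can give. At E17.5 the score was 0.0041 with 3 or more AUUUA (exact permutation p = 0.657) and 0.0536 without the libraries in doubt (exact permutation p = 0.1, the smallest 3 against 3 can give). At P0 it was 0.0341 without the library labelled control 2 (exact permutation p = 0.0286). At P5 it was 0.0184 with 1 or more UAUUUAU and 0.0555 with 3 or more AUUUA (exact permutation p = 0.0286 for both). At P16 it turned from -0.0012 to 0.0134 with 1 or more UAUUUAU (exact permutation p = 0.0286). With 1 library left out it ranged from 0.0993 to 0.1201 at E14.5, 0.0561 to 0.0656 at E17.5, 0.0202 to 0.0341 at P0, 0.0124 to 0.0255 at P5 and -0.0073 to 0.0055 at P16.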

Other observations

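Lists that camera called at no stage included reported ZFP36 targets: 6 up, 2 down of 16 at E14.5 (adjusted p = 0.0656), 4 up, 5 down of 16 at E17.5 (adjusted p = 0.65), 3 up, 1 down of 17 at P0 (adjusted p = 0.98), 0 up, 1 down of 17 at P5 (adjusted p = 0.328), 2 up, 1 down of 18 at P16 (adjusted p = 0.232). Mitosis genes gave 2 up, 3 down of 20 at E14.5 (adjusted p = 0.994), 3 up, 0 down of 20 at E17.5 (adjusted p = 0.418), 0 up, 0 down of 20 at P0 (adjusted p = 0.41), 0 up, 0 down of 20 at P5 (adjusted p = 0.897), 1 up, 0 down of 10 at P16 (adjusted p = 0.95). For the Notch pathway the counts were 5 up, 2 down of 22 at E14.5 (adjusted p = 0.0703), 0 up, 5 down of 22 at E17.5 (adjusted p = 0.119), 1 up, 1 down of 22 at P0 (adjusted p = 0.0522), 0 up, 0 down of 22 at P5 (adjusted p = 0.165), 2 up, 0 down of 21 at P16 (adjusted p = 0.876). Immediate early genes gave 3 up, 0 down of 16 at E14.5 (adjusted p = 0.809), 3 up, 2 down of 15 at E17.5 (adjusted p = 0.277), 1 up, 1 down of 16 at P0 (adjusted p = 0.27), 1 up, 1 down of 16 at P5 (adjusted p = 0.399), 3 up, 0 down of 20 at P16 (adjusted p = 0.114). Sex-linked genes gave 0 up, 0 down of 5 at E14.5 (adjusted p = 0.626), 0 up, 0 down of 5 at E17.5 (adjusted p = 0.463), 0 up, 0 down of 4 at P0 (adjusted p = 0.325).

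The 2 hypotheses below were tested after the DKO effects had been seen. DKO retinas may lie further along the control time course at P0: on the line from control E17.5 to control P5 they stood 16.28 percent further (38.8 ± 6.41 against 22.47 ± 1.1, n = 4, exact p = 0.0286, adjusted p = 0.0715 over 5 stages). The shift was 8.98 at E17.5, -1.69 at E14.5, 4.10 at P5 and -4.85 at P16. The test cannot tell a shift in timing from a change in single cell types. Cell counts by birth date would separate them.

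DKO libraries may differ from each other because recombination was unequal. Over 20 DKO libraries, stage-centred Gm36660 and position along the DKO effect correlated at r = 0.903 (95% interval 0.767 to 0.961, permutation p = 0.00019, rho = 0.896 with p = 3e-05, adjusted p = 0.00057 over 3 measures). Without the 2 farthest libraries r was 0.795 (permutation p = 0.00326). Among 26 other genes called in 1 direction at 4 or more stages r ran from 0.261 to 0.863, so a high r is not special to Gm36660. Abcd4, beside Vsx2 and perhaps a mark of the transgene, gave r = -0.34 (interval -0.68 to 0.121, p = 0.0878, rho = -0.519 with p = 0.0269, adjusted p = 0.132), and library size r = 0.047 (interval -0.404 to 0.48, p = 0.813, rho = 0.042 with p = 0.872). Library size stays open, as does the transgene, since the interval for Abcd4 reaches above 0 and nothing here shows that Abcd4 tracks it. Allele-specific PCR in each sample could settle this.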
